A study of Mus musculus with 3 samples.

How the data were processed

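The series holds 3 droplet single-cell RNA libraries of sorted mouse bone marrow niche cells, 1 library for each of 3 groups. Per the labels' protocols, the WT library came from untreated female CB6F1 mice, a cross of BALB/c and C57BL/6. For the BMT (bone marrow transplantation) library, female CB6F1 recipients were irradiated with 2 doses of 4.0 Gy. They received nucleated marrow cells of B6.SJL donors, which carry the CD45.1 form of CD45, 4 hours after irradiation. For the aGVHD (acute graft-versus-host disease) library, such recipients also received spleen cells of female C57BL/6 donors. Per the same protocols, the marrow was depleted of cells stained for CD45, a lineage antibody mix or CD71, and live cells were kept with Calcein AM and DAPI. The number of mice per library, the days between transplantation and collection, and the sex of the marrow donors are not given in the sources used here.

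The deposited files are raw counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, with no normalisation. Per the submitters' processing notes, the authors used Cell Ranger with the mm10 genome build, and Seurat. Per the file headers, the matrices were written by Cell Ranger 3.1.0. Each matrix lists 27998 genes and 6794880 barcodes, so empty droplets are included and cells had to be called here. The library totals were 86575425 UMIs for WT, 44219063 for BMT and 67439098 for aGVHD. The immunoglobulin and T cell receptor constant-region genes searched for were missing from the gene list and were not analysed here.

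A barcode was called a cell with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs. The mitochondrial limit removed 544, 253 and 548 barcodes in WT, BMT and aGVHD. Likely doublets were taken as the highest Scrublet scores, at 0.8% per 1000 called cells, which removed 407, 105 and 248 cells. Scrublet's own threshold would have removed 187, 35 and 78. Counts were scaled per cell and log-transformed, and 2000 variable genes were chosen with the library as batch key. Mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes were kept out of this choice. Joint Leiden clustering used 30 principal components, 15 neighbours and resolution 1, with seed 1, and gave 32 clusters.

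Clusters were named from 19 marker lists fixed before the data were examined. A cluster took the class with the highest mean marker level over the clusters' median on the log2 scale. The score had to be at least 1.5, at least 0.5 above the next class, with at least 3 markers detected and no other class holding more markers among the 10 leading genes. These naming limits were set after the clusters were seen, so each class is a resemblance ("-like") and the unnamed share is given per library. A cluster called led by a gene held that gene among its 20 leading genes, not always in first place. Shares of cells carry exact Clopper-Pearson 95% intervals. Ratios of shares carry 95% intervals from the normal approximation on the log scale, which also cover counting error only.

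Within a class, UMIs were summed over the cells of each library and expressed as CPM, a gene's UMIs scaled to the same total of UMIs in every class and library. The ratio of 2 libraries carries its exact 95% interval conditional on the summed counts. A gene with 0 UMIs in a class and library was set to a floor of 3 UMIs, and its fold against that floor is given with the lower limit of the exact interval. A gene passed the size rule when it had at least 50 UMIs over both libraries, differed at least 2-fold, had an interval excluding 1, and stood at least 2 times above the same library's empty droplets (barcodes of at most 100 UMIs) on its higher side. For each of 23 gene lists fixed before the data were examined, the median log2 fold over members with at least 50 UMIs was taken, with its order-statistic 95% interval. Its percentile among 10000 random lists of the same size, matched on mean level, serves as a description. Members were counted as higher or lower at a 1.5-fold boundary. With 1 library per group there is no replicate spread, so no test was run and no p-value exists. Intervals of shares, levels and ratios cover counting error only. Intervals of list medians describe the spread among the measured members, taken as independent, and do not cover counting error or spread between mice.

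The genes named in the text follow a rule fixed before the data were examined. In the 2 non-haematopoietic classes with the most cells in their smallest library, the 6 genes higher and the 6 genes lower in BMT over WT and in aGVHD over BMT were taken, ranked by the interval bound nearest to 1, among genes past the size rule. Ribosomal, mitochondrial, haemoglobin and immunoglobulin genes and unnamed gene models were excluded. Fixed sets of niche genes and endothelial genes, and the members of each list with the most UMIs, are reported as well, whether or not they pass the size rule. This rule selected the LepR stromal-like and the endothelial-like classes. Symbols and gene identifiers are those of the deposited gene list. Positions are from the mm10 annotation, in which all 68 identifiers looked up were found.

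The fold and list code was tested on simulated data, with counts drawn from the class totals. It recovered 98 to 100% of genes changed at least 3-fold, and 0 to 2 of 5314 to 9339 unchanged genes passed the size rule. Apart from the set changes, both simulated libraries shared the same profile, with counting error only and no free RNA. The simulation therefore checks the code and does not give the rate of false calls between real libraries.

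Alternatives fixed before the data were examined covered cell calling, the mitochondrial limit, doublets, clustering resolution, separate clustering, scaling, averaging, free-RNA subtraction, gene minimums and depth. Alternatives added after seeing the data took the endothelial clusters apart, left mitochondrial and rRNA-derived genes out of the totals, and limited lists to members above the empty-droplet level. Free-RNA subtraction was extended to the fibroblast-like and mural-like classes after seeing the data, with the share set from haemoglobin and neutrophil granule genes. In BMT and aGVHD a second share was taken as the level of Y-linked genes in the class over their level in empty droplets. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.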

Results

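Single-cell RNA libraries of sorted bone marrow niche cells were collected from 3 groups of CB6F1 mice, with 1 library per group. The WT group was untreated, the BMT group was irradiated and given B6.SJL bone marrow, and the aGVHD group also received C57BL/6 spleen cells. The comparison of BMT with WT asked how niche cells differed after irradiation and marrow transfer. The comparison of aGVHD with BMT asked what differed when spleen cells, the source of the graft-versus-host reaction, were given in addition. After cell calling, the libraries held 6722 cells for WT, 3516 for BMT and 5320 for aGVHD. Median depth was 7122 UMIs per cell in WT, 6706.5 in BMT and 6800 in aGVHD. Because each group had 1 library, no replicate check was possible, and every difference below describes these 3 libraries. Intervals of shares, levels and ratios cover counting error only, and those of list medians describe the spread among list members.

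Niche classes made up a different part of each library. Cells named as a non-haematopoietic class were 5331 of 6722 cells (79.3%) in WT, 2055 of 3516 (58.4%) in BMT and 2298 of 5320 (43.2%) in aGVHD. Unnamed cells were 6.11% of WT, 8.30% of BMT and 15.9% of aGVHD. Endothelial-like cells, a class of vessel-lining cells, were 8.87% (95% interval 8.12 to 9.67) of named non-haematopoietic cells in WT, 37.8% (35.7 to 39.9) in BMT and 53.5% (51.4 to 55.5) in aGVHD. Which vessels they came from was not determined. Fibroblast-like cells were 42.2% (40.9 to 43.5) in WT, 16.5% (14.96 to 18.22) in BMT and 19.1% (17.5 to 20.7) in aGVHD. LepR stromal-like cells, the main source of Cxcl12 and Kitl in marrow, were 17.8% (16.8 to 18.9) in WT, 28.4% (26.4 to 30.4) in BMT and 17.7% (16.1 to 19.3) in aGVHD. Osteolineage-like cells were 6.04% (5.42 to 6.71) in WT, 7.40% (6.30 to 8.61) in BMT and 1.61% (1.14 to 2.21) in aGVHD. Chondrocyte-like cells were 13.1% in WT, 1.80% in BMT and 1.52% in aGVHD. These shares describe what passed a sort depleting CD45, lineage and CD71 stained cells, not the marrow itself.

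**Figure D1:**
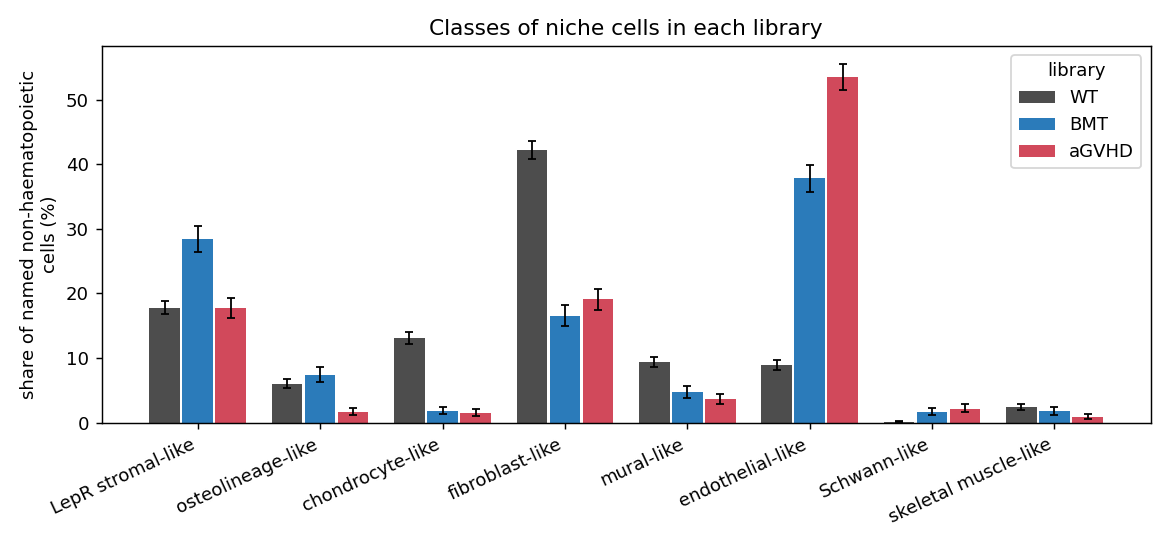
Share of each non-haematopoietic class among named non-haematopoietic cells in WT, BMT and aGVHD, with exact 95% intervals for counting error.

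The ratio of endothelial-like shares was 4.26 (95% interval 3.85 to 4.72) for BMT over WT and 1.41 (1.32 to 1.51) for aGVHD over BMT. The ratio of LepR stromal-like shares was 1.59 (1.46 to 1.74) for BMT over WT and 0.623 (0.557 to 0.696) for aGVHD over BMT. For fibroblast-like cells it was 0.392 (0.354 to 0.434) and 1.15 (1.01 to 1.31), and for osteolineage-like cells 1.22 (1.02 to 1.48) and 0.218 (0.153 to 0.310). Within the osteolineage, a cluster led by Bglap, the gene of the osteoblast protein osteocalcin, held 155 WT cells, 85 BMT cells and 0 aGVHD cells. For aGVHD, 0 of 2298 cells allows a share of up to 0.131% at 3 counts, with an exact upper limit of 0.160%. A second osteolineage cluster, led by the periosteal matrix gene Postn, held 167 WT, 67 BMT and 37 aGVHD cells. The LepR ratio for aGVHD over BMT was 1.06 under a library-specific UMI minimum, the fibroblast ratio was 0.776 at clustering resolution 2, and the osteolineage ratio for BMT over WT was 0.746 when each library was clustered alone. With likely doublets kept, the osteolineage ratio for aGVHD over BMT was 0.0105.

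In LepR stromal-like cells, interferon-induced genes were far higher in BMT than in WT. The T cell chemokine gene Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) was at 8907 CPM in BMT and 155 CPM in WT, 57.3-fold higher (95% interval 53.6 to 61.3). Gbp4 (ENSMUSG00000079363, chromosome 5, 105115767 to 105139586), a GTPase gene induced by interferon gamma, was 185-fold higher (97.51 to 406). The bone sialoprotein gene Ibsp (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469) was at 257 CPM in BMT and 5008 CPM in WT, 19.5-fold lower (18.6 to 20.4). The niche chemokine gene Cxcl12 stayed the most abundant niche factor and was 1.61-fold lower (1.60 to 1.62), at 16998 CPM in BMT and 27375 CPM in WT.

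The other genes with the largest folds in this class follow the same rule of choice. The carbonic anhydrase gene Car3 was 58.8-fold higher in BMT than in WT (41.3 to 86.7). Car3 is a gene of fat cells and was also among the leading genes of the Bglap-led osteolineage cluster. Gbp8 was 44.0-fold higher (23.03 to 96.75). Gbp10 was 200-fold higher (35.7 to 7945), with 1 UMI in WT. The antiviral gene Mx1 had no UMIs in WT and was 34.2-fold higher against a floor of 3 UMIs, with a lower 95% limit of 27.5. Gbp4, Gbp8 and Gbp10 are close paralogs, so the split of reads among them is uncertain. The protease inhibitor gene A2m was 16.3-fold lower (12.3 to 21.9), and the claudin gene Cldn10 was 10.8-fold lower (8.65 to 13.7). Cbfa2t3, a transcriptional corepressor gene, was 5.47-fold lower (4.37 to 6.91), Angptl1 was 5.03-fold lower (4.38 to 5.80) and Greb1 was 4.76-fold lower (3.53 to 6.51).

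Whole gene lists separated in the same class. Of 28 interferon gamma response genes measured in LepR stromal-like cells, 24 were higher in BMT than in WT, 0 lower and 4 neither, with a median log2 fold of 2.86 (1.60 to 3.52). Within it, Iigp1 was 12.5-fold higher (11.7 to 13.3) and Cxcl10 12.7-fold higher (11.8 to 13.8). The type I interferon response list had a median of 2.48 (1.86 to 3.13), with 24 of 25 members higher, among them Irf7 at 11.04-fold. In the MHC class I list, 13 of 14 members were higher, with a median of 1.57 (0.86 to 1.75), and B2m was 1.98-fold higher. All 6 measured MHC class II genes, which present antigen to CD4 T cells, were higher, with a median of 5.18 (3.75 to 5.60). Cd74, the invariant chain gene, was at 417 CPM in BMT and 13.6 CPM in WT. BMT empty droplets held Cd74 at 287 CPM, so it did not pass the size rule. Too few members of the MHC class II list stood 2 times above the empty droplets to give a median. Of 26 p53 target genes, 17 were higher, 1 lower and 8 neither, including Cdkn1a at 2.55-fold (2.41 to 2.71). The adipogenic list had a median of 1.07 (0.10 to 1.84), with Lpl 3.59-fold and Fabp4 5.54-fold higher, and 0.37 when only members above the empty-droplet level were kept. The median of all measured genes was itself 0.13 on the log2 scale.

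The haematopoietic niche factor list differed little as a whole between WT and BMT. Of 24 members in LepR stromal-like cells, 6 were higher, 4 lower and 14 neither, with a median log2 fold of -0.11 (-0.50 to 0.28). Il7, a growth factor gene for B cell precursors, was 1.94-fold higher in BMT than in WT (1.79 to 2.09). Angpt1 was 1.53-fold higher (1.41 to 1.66), and Kitl was nearly equal at 1.04-fold (1.01 to 1.07). The leptin receptor gene Lepr was 1.52-fold lower (1.48 to 1.57), Adipoq 1.38-fold lower (1.35 to 1.41) and Vcam1 1.30-fold lower (1.28 to 1.33). Csf1 was 1.13-fold lower (1.08 to 1.19). Spp1 and Col1a1 lay below the empty-droplet level in both libraries. In total 281 genes were at least 2-fold higher and 96 at least 2-fold lower among 10453 measured in LepR stromal-like cells. Over the alternative settings the number higher ran from 154 to 357 and the number lower from 54 to 132. WT cells lay almost wholly in a cluster with Adipoq, Cxcl12 and Lepr among its leading genes (923 of 949). BMT cells lay almost wholly in a cluster led by Cxcl9 (575 of 583). Their median depth was 5711 UMIs in WT and 14388 in BMT, and the part of their UMIs attributed to free RNA from haemoglobin and granule genes was 11.5% in WT and 0.972% in BMT, while Y-linked UMIs gave 2.61% in BMT.

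**Figure D2:**
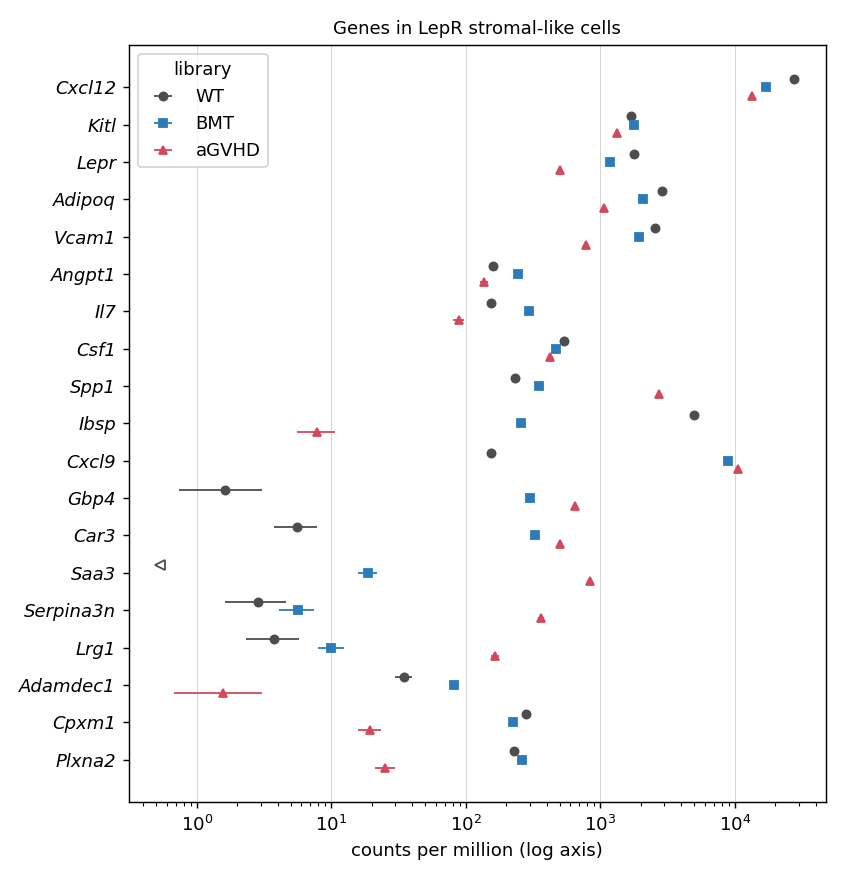
Levels of niche genes and of the genes with the largest folds in LepR stromal-like cells of WT, BMT and aGVHD, with intervals for counting error. Open triangles mark genes without UMIs, at the level of 3 UMIs.

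In endothelial-like cells, Cd74 and Gdf15 were higher and the adhesion genes Selp, Sele and Vwf lower in BMT than in WT. The invariant chain gene Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) was 21.0-fold higher (16.7 to 26.8), at 750 CPM in BMT and 35.7 CPM in WT. It was 51.0-fold higher within the Selp-led cluster (38.8 to 68.3), while the Gpihbp1-led clusters gave 2.60-fold with an interval holding 1 (0.687 to 22.01). Gdf15, a stress cytokine gene induced by p53, was 21.4-fold higher (15.8 to 29.6) and was higher in both cluster groups. The P-selectin gene Selp (ENSMUSG00000026580, chromosome 1, 164115264 to 164150026), which captures leukocytes from blood, was 10.1-fold lower (8.87 to 11.5). Within the cluster led by Selp it was still 5.22-fold lower (4.43 to 6.19). The E-selectin gene Sele was 4.71-fold lower (4.01 to 5.53) and the von Willebrand factor gene Vwf 7.59-fold lower (6.36 to 9.09), against 2.33-fold and 3.55-fold lower within the Selp-led cluster.

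Further genes were selected in the endothelial class by the same rule. Eda2r, a p53 target, was 21.99-fold higher in BMT than in WT (9.29 to 68.4), Tgtp2 was 20.04-fold higher (11.6 to 37.9) and Ifit2 13.3-fold higher (8.45 to 22.3). Tgtp2 and Tgtp1 are close paralogs, so this assignment is uncertain. Gbp10 had no UMIs in WT and was 9.24-fold higher against the floor of 3 UMIs, with a lower 95% limit of 7.28. On the lower side, the contractile gene Tagln was 17.1-fold lower (14.8 to 19.8) and Nt5e 15.3-fold lower (10.2 to 23.9). The colony-stimulating factor gene Csf3 was 9.60-fold lower (6.59 to 14.3), the venular chemokine receptor gene Ackr1 9.54-fold lower (7.81 to 11.7) and the prostaglandin transporter gene Slco2a1 8.91-fold lower (7.42 to 10.7). Within the Selp-led cluster Tagln was 6.47-fold lower, Ackr1 4.16-fold and Slco2a1 4.73-fold lower.

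The interferon, MHC class I and p53 target lists were higher in endothelial-like cells of BMT as well. Of 28 interferon gamma response genes, 26 were higher in BMT than in WT, 0 lower and 2 neither, with a median log2 fold of 1.98 (1.65 to 2.32). Gbp4 was 5.00-fold and Psmb8 3.14-fold higher. All 24 measured type I interferon response genes were higher, with a median of 1.66 (1.54 to 2.39). MHC class I genes had a median of 1.59 (0.91 to 2.57) with 13 of 14 higher, and H2-K1 was 3.05-fold higher. In BMT, H2-K1 was at 3126 CPM and Psmb8 at 544 CPM, against 2919 and 334 CPM in empty droplets, so neither passed the size rule. With free RNA subtracted, H2-K1 was 2.93-fold and Psmb8 3.04-fold higher. The p53 target list had a median of 1.27 (0.66 to 1.70), with 18 of 23 higher, 0 lower and 5 neither. In it, the cell cycle inhibitor gene Cdkn1a was 3.90-fold higher (3.61 to 4.21) and Bax 2.99-fold higher. Of 18 sinusoidal endothelium genes, 0 were higher, 8 lower and 10 neither, with a median of -0.54 (-1.53 to -0.34), and it was -0.50 within the Selp-led cluster and -0.29 (-1.08 to 0.31) within the Gpihbp1-led clusters. Of 17 leukocyte adhesion genes, 1 was higher, 5 lower and 11 neither, with a median of -0.10 (-0.90 to 0.17).

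Among the fixed endothelial genes, the stem cell factor gene Kitl was 2.21-fold higher in BMT than in WT (2.04 to 2.40). Ly6a was 2.70-fold higher (2.54 to 2.86), Sox17 1.73-fold higher (1.55 to 1.94), Cdh5 1.40-fold higher (1.34 to 1.47) and Kdr 1.33-fold higher (1.24 to 1.42). Icam1 was 2.05-fold lower (1.83 to 2.30), Jag1 1.75-fold lower (1.43 to 2.13), Emcn 1.46-fold lower (1.37 to 1.56) and Stab2 1.27-fold lower (1.06 to 1.51). For Flt4 and Dll4 the interval of the ratio held 1. Cxcl12 lay below the empty-droplet level in this class. In total 222 genes were at least 2-fold higher (123 to 272 over the alternative settings) and 171 at least 2-fold lower (76 to 248) among 8657 measured. The Selp-led cluster held 328 of 473 endothelial-like cells in WT and 113 of 777 in BMT, so the class differs in make-up as well. Inside the Gpihbp1-led clusters Icam1 was 3.34-fold higher (1.60 to 8.40) on 7 UMIs in WT, the opposite direction to the whole class.

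Interferon response lists were also higher in fibroblast-like and mural-like cells, with fewer than 3 members of each list above 2 times the empty-droplet level. In fibroblast-like cells, the MHC class I gene H2-K1 was at 842 CPM in BMT and 180 CPM in WT, both below the empty-droplet level, so it did not pass the size rule. The part of fibroblast-like UMIs attributed to free RNA was 6.10% in WT and 7.68% in BMT, and with that part subtracted H2-K1 was 4.30-fold higher (4.08 to 4.53). Of 25 interferon gamma response genes measured in fibroblast-like cells, 22 were higher, 0 lower and 3 neither, with a median log2 fold of 1.89 (0.97 to 2.82), and 1.67 (0.73 to 2.61) with free RNA subtracted. Their p53 target list had a median of 0.21, with 7 higher, 2 lower and 17 neither. In mural-like cells, 14 of 18 interferon gamma response genes were higher, with a median of 2.09, and 2.42 (0.53 to 2.94) with free RNA subtracted. The part attributed to free RNA in mural-like cells was 14.2% in WT and 1.30% in BMT, while Y-linked UMIs gave 5.46% in BMT.

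In LepR stromal-like cells of aGVHD, Saa3 and Serpina3n were much higher than in BMT, while Vcam1 and Il7 were lower. The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) was at 837 CPM in aGVHD and 18.7 CPM in BMT, 44.7-fold higher (38.0 to 52.9). The protease inhibitor gene Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329) was 64.5-fold higher (48.2 to 88.5). Vcam1, which holds blood progenitors in the niche, was 2.496-fold lower (2.41 to 2.58), and Il7 was 3.34-fold lower (3.02 to 3.70). Ibsp was at 7.80 CPM in aGVHD and 257 CPM in BMT, both below the empty-droplet level of the same library, so it did not pass the size rule.

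Beyond these, the imprinted RNA gene H19 was 71.3-fold higher in aGVHD than in BMT (34.2 to 179). Lrg1 was 16.5-fold higher (13.1 to 21.0) and the lipid droplet gene Plin4 16.2-fold higher (10.8 to 25.2). Serpina3m had no UMIs in BMT and was 34.0-fold higher against the floor of 3 UMIs, with a lower 95% limit of 26.9. As a close paralog of Serpina3n its assignment is uncertain. The metalloproteinase-like gene Adamdec1 (ENSMUSG00000022057, chromosome 14, 68563380 to 68582095) was 52.9-fold lower (26.7 to 123). Pappa2, which cleaves growth factor binding proteins, had no UMIs in aGVHD. It was 22.8-fold lower against the floor of 3 UMIs, with a lower 95% limit of 18.2. Nrep was 14.7-fold lower (9.20 to 25.1), Cd83 14.5-fold lower (8.37 to 27.6), Cpxm1 11.6-fold lower (9.51 to 14.4) and the semaphorin receptor gene Plxna2 10.3-fold lower (8.66 to 12.5).

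Most of the fixed niche genes were lower in aGVHD than in BMT in the LepR stromal-like class. Lepr was 2.33-fold lower (2.23 to 2.44), Adipoq 1.97-fold lower (1.91 to 2.03) and Angpt1 1.78-fold lower (1.63 to 1.94). Kitl was 1.34-fold lower (1.30 to 1.38), Cxcl12 1.26-fold lower (1.25 to 1.28) and Csf1 1.11-fold lower (1.05 to 1.17). Spp1, the osteopontin gene, was 7.78-fold higher (7.47 to 8.10), at 2723 CPM in aGVHD. Of 25 niche factor genes, 3 were higher, 10 lower and 12 neither, with a median log2 fold of -0.39 (-0.83 to -0.15). The median of all measured genes was -0.14, so part of that list value is a shift of the whole class.

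In the LepR stromal-like class, MHC class II genes were higher in aGVHD than in BMT and MHC class I genes were not. All 6 MHC class II genes were higher again, with a median of 1.21 (0.79 to 1.35), and Cd74 was 2.55-fold higher (2.44 to 2.66). Of 14 MHC class I genes, 0 were higher, 1 lower and 13 neither, with a median of -0.07 (-0.30 to 0.31). Of 24 NF-kB and inflammatory genes, 13 were higher, 2 lower and 9 neither, with a median of 0.62 (-0.00 to 0.82), including the complement gene C3 at 4.16-fold (3.94 to 4.39) and Ccl2 at 1.76-fold (1.70 to 1.82). The interferon gamma response list differed little, with 7 higher, 1 lower and 20 neither. Of 25 type I interferon response genes, 1 was higher, 7 lower and 17 neither, with a median of -0.43 (-0.52 to -0.25), and Bst2 was 1.83-fold lower. The osteogenic list had a median of -1.34 (-2.81 to -0.41), which was -0.38 when only the 6 members above the empty-droplet level were kept. In total 146 genes were at least 2-fold higher and 396 at least 2-fold lower among 10413 measured. Over the alternative settings, the number higher ran from 90 to 181 and the number lower from 166 to 498, the lowest with cells thinned to equal depth.

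In endothelial-like cells of aGVHD, Ido1 and Cd274, whose products restrain T cells, were much higher than in BMT. Ido1 (ENSMUSG00000031551, chromosome 8, 24584136 to 24597009), which degrades tryptophan, was at 128 CPM in aGVHD and 5.08 CPM in BMT, 25.3-fold higher (16.5 to 40.7), and 19.0-fold higher within the Gpihbp1-led clusters (12.5 to 30.6). Cd274, the gene of the checkpoint ligand PD-L1, was 6.12-fold higher (5.515 to 6.803). It was 5.60-fold higher within the Gpihbp1-led clusters and 2.49-fold higher within the Selp-led cluster. The sinusoidal hyaluronan receptor gene Stab2 was 6.17-fold lower (4.64 to 8.33), and the cluster led by it held 81 of 777 cells in BMT and 18 of 1229 in aGVHD. The apelin receptor gene Aplnr was 6.76-fold lower (5.14 to 9.01), and 11.6-fold lower within the Gpihbp1-led clusters (6.99 to 20.4).

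Other selected endothelial genes included Apol7c (ENSMUSG00000044309, chromosome 15, 77524852 to 77533316), which was 58.4-fold higher in aGVHD than in BMT (19.7 to 286). AA467197 was 8.23-fold higher (6.85 to 9.95), the interferon-induced transcription factor gene Batf2 7.38-fold higher (5.48 to 10.1) and the hypoxia-induced gene Ankrd37 7.26-fold higher (5.34 to 10.1). Gkn3 had no UMIs in aGVHD and was 47.1-fold lower against the floor of 3 UMIs, with a lower 95% limit of 37.8. The thromboxane receptor gene Tbxa2r was 19.9-fold lower (7.47 to 74.7), Chp2 19.0-fold lower (6.18 to 94.7) on 3 UMIs in aGVHD, and Ces2e 18.8-fold lower (8.38 to 52.3).

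The interferon gamma response list was higher in endothelial-like cells of aGVHD. Of 29 genes, 24 were higher in aGVHD than in BMT, 1 lower and 4 neither, with a median log2 fold of 1.12 (0.82 to 1.34). Gbp4 was 2.96-fold and Psmb8 2.16-fold higher. MHC class I genes had a median of 0.74 (0.49 to 1.18), with 10 higher, 1 lower and 3 neither, and H2-K1 was 1.52-fold higher. MHC class II genes had a median of 0.82 (0.40 to 0.91) in the whole class, 4.09 in the Gpihbp1-led clusters and 1.26 in the Selp-led cluster. Type I interferon response genes did not differ as a list, with 4 higher, 1 lower and 20 neither. Of 22 extracellular matrix genes, 1 was higher, 17 lower and 4 neither, with a median of -1.16 (-1.95 to -0.68), and -0.72 (-1.95 to -0.13) over the 7 members above the empty-droplet level. Sparc was 2.56-fold lower (2.47 to 2.66) but lay below the empty-droplet level in BMT, so it did not pass the size rule. The arterial endothelium list had a median of -0.79 (-1.29 to -0.15), with 4 higher, 13 lower and 6 neither.

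Of the fixed endothelial genes, Ly6a was 2.10-fold higher in aGVHD than in BMT (2.04 to 2.16), and the Notch ligand gene Dll4 was 2.06-fold higher (1.82 to 2.33). Icam1 was 1.28-fold higher (1.15 to 1.42). Kdr, the main receptor for vascular endothelial growth factor, was 2.06-fold lower (1.94 to 2.18). Emcn was 1.92-fold lower (1.79 to 2.05), Kitl 1.67-fold lower (1.58 to 1.77), Sox17 1.63-fold lower (1.496 to 1.772), Cdh5 1.44-fold lower (1.38 to 1.49) and Flt4 1.33-fold lower (1.14 to 1.56). For Vwf and Jag1 the interval held 1. Sele was 7.33-fold lower (4.99 to 11.1) in the whole class and 5.16-fold lower within the Selp-led cluster (3.02 to 9.48). In total 143 genes were at least 2-fold higher (99 to 179 over the alternative settings) and 185 at least 2-fold lower (85 to 260) among 9145 measured. The Gpihbp1-led clusters held 583 of 777 endothelial-like cells in BMT and 1136 of 1229 in aGVHD. They are 2 clusters, and 529 of the BMT cells lay in the one that held 26 aGVHD cells, while 1110 of the aGVHD cells lay in the one that held 54 BMT cells. The sinusoidal endothelium median was -0.71 in the whole class but 0.52 within the Gpihbp1-led clusters and 0.27 within the Selp-led cluster.

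**Figure D3:**
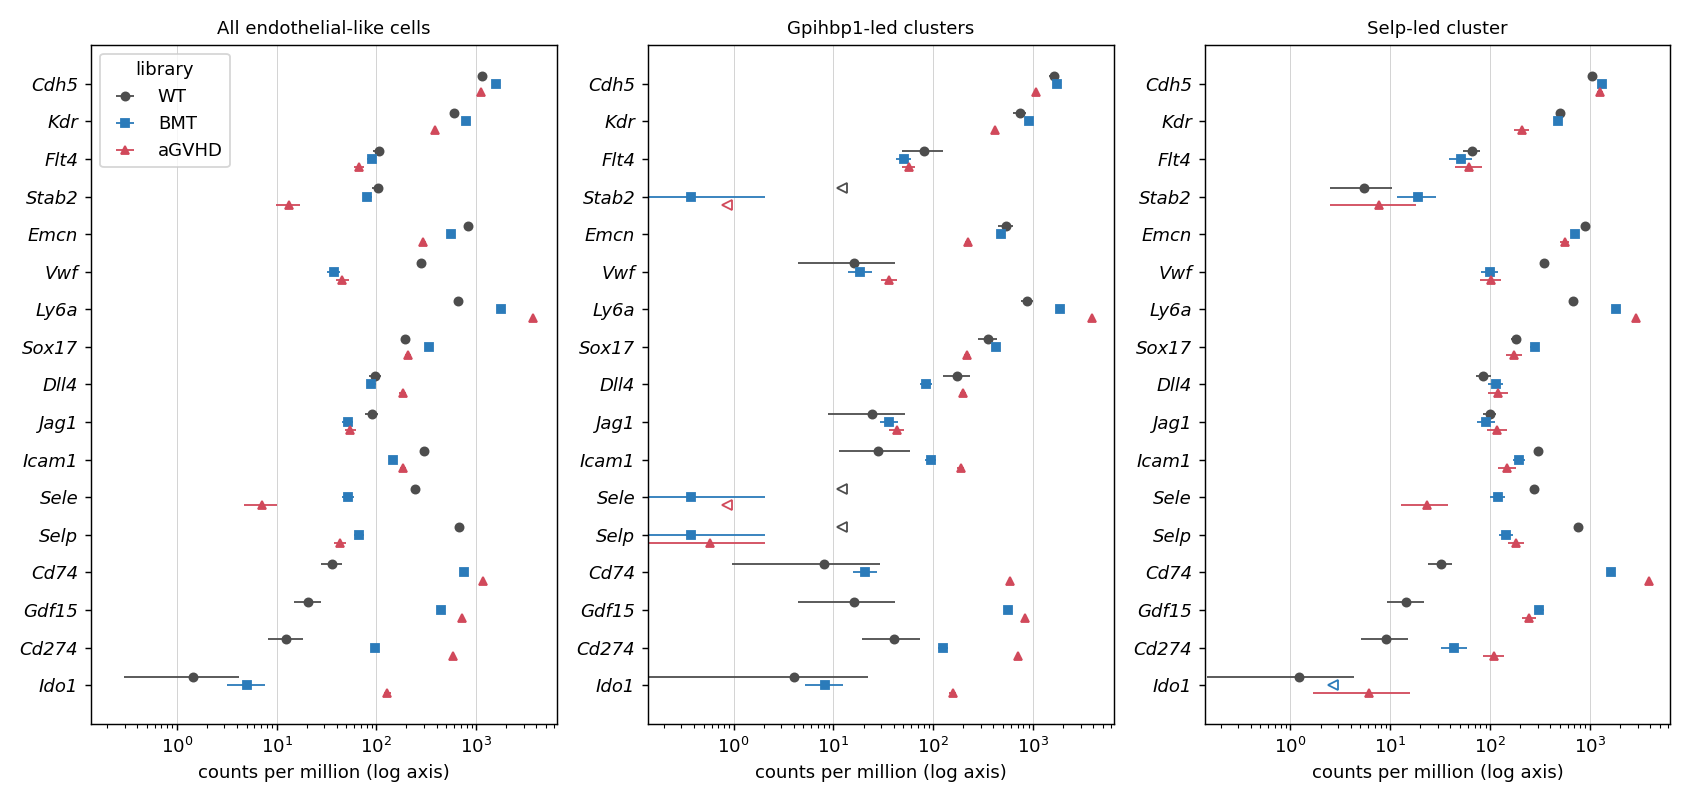
Levels of fixed endothelial genes and of the genes with the largest folds in all endothelial-like cells, the Gpihbp1-led clusters and the Selp-led cluster of WT, BMT and aGVHD. Open triangles mark genes without UMIs, at the level of 3 UMIs.

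Fibroblast-like cells of aGVHD had the largest interferon gamma response median over BMT among the 4 classes compared. Of 27 interferon gamma response genes in fibroblast-like cells, 24 were higher, 0 lower and 3 neither, with a median log2 fold of 2.11 (1.62 to 2.40). Over the 10 members above the empty-droplet level it was 2.001 (1.01 to 2.72), with 9 higher and 0 lower. Type I interferon response genes had a median of 1.18 (0.78 to 1.60), with 19 of 22 higher, and Ifit1 was 4.15-fold higher. All 13 measured MHC class I genes were higher, with a median of 1.62, and 1.71 (1.42 to 2.70) with free RNA subtracted. In these aGVHD cells H2-K1 was at 2165 CPM and B2m at 5015 CPM, against 2005 and 2569 CPM in empty droplets. Neither passed the size rule. Median depth of fibroblast-like cells was 11126.5 UMIs in BMT and 4360.5 in aGVHD, and thinning to equal depth was not run for them. The complement gene C3 was 4.53-fold higher. Of 30 extracellular matrix genes, 1 was higher, 18 lower and 11 neither, with a median of -0.71 (-1.37 to -0.39), and the collagen gene Col3a1 was at 1029 CPM in aGVHD and 5430 CPM in BMT. Col1a1 did not exceed the empty-droplet level in BMT and did not pass the size rule. In mural-like cells, 11 of 12 MHC class I genes were higher, with a median of 1.12, and 0.98 (0.62 to 1.47) with free RNA subtracted. Free RNA was 18.4% of their UMIs in aGVHD, while Y-linked UMIs gave 24.8%. In mural-like cells of aGVHD, H2-K1 and B2m were at 2003 and 2997 CPM, against 2005 and 2569 CPM in empty droplets, and neither passed the size rule.

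**Figure D4:**
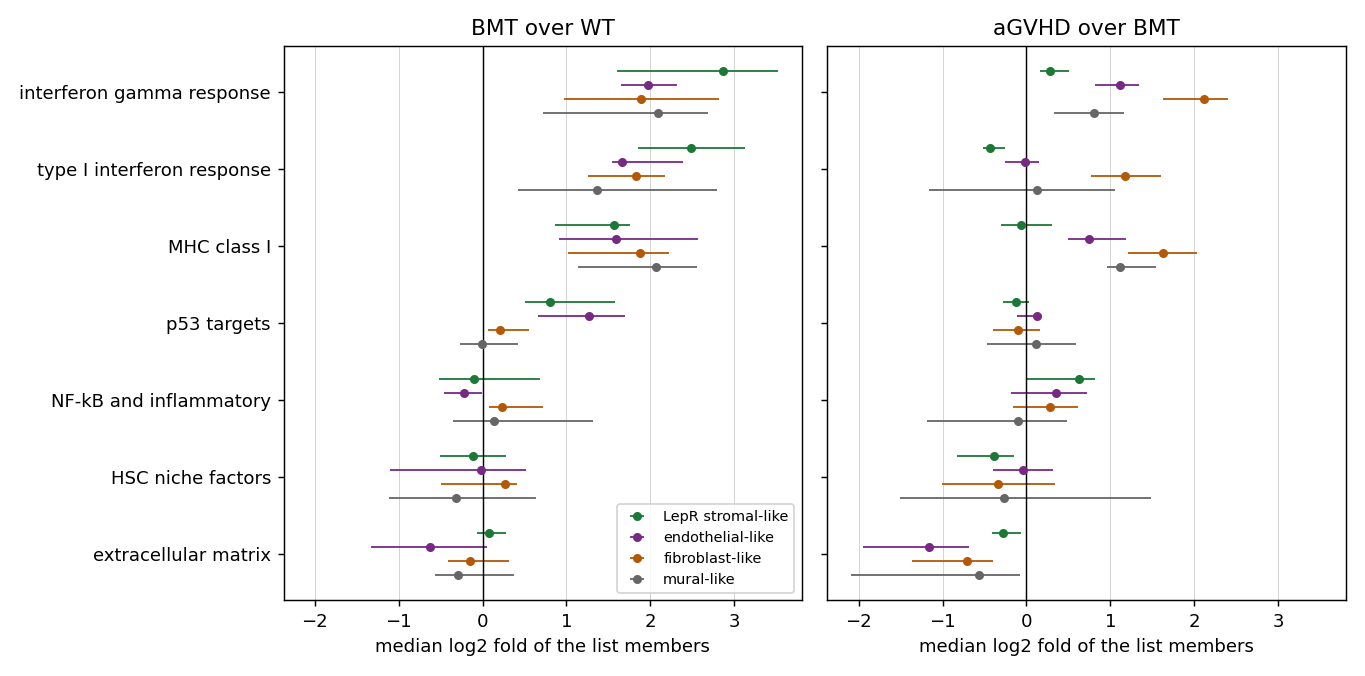
Median log2 fold of gene lists for BMT over WT and aGVHD over BMT in LepR stromal-like, endothelial-like, fibroblast-like and mural-like cells.

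Against WT, the aGVHD library held part of both sets of differences. In LepR stromal-like cells, Cxcl12 was 2.04-fold lower in aGVHD than in WT (2.02 to 2.06), Lepr 3.56-fold lower (3.41 to 3.71), Vcam1 3.26-fold lower (3.14 to 3.37) and Ibsp 642-fold lower (471 to 899). Of their 28 interferon gamma response genes, 25 were higher and 0 lower, with a median log2 fold of 3.24 (1.61 to 3.85). Il7, higher in BMT, was 1.73-fold lower in aGVHD than in WT (1.54 to 1.94). Their niche factor list had a median of -0.43 (-0.89 to -0.16), with 2 higher, 11 lower and 12 neither. In endothelial-like cells, 28 of 29 interferon gamma response genes were higher in aGVHD than in WT, with a median of 3.07 (2.67 to 3.57). All 14 of their MHC class I genes were higher, with a median of 2.26. Of 18 sinusoidal endothelium genes, 0 were higher and 16 lower, with a median of -2.09, but it was -0.28 within the Gpihbp1-led clusters and -0.60 within the Selp-led cluster. Fibroblast-like cells had an interferon gamma response median of 4.14.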

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

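The tests in this part were chosen after the result was seen. Some list differences between classes and the Y-linked counts fell outside the questions asked and are set out here.

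For BMT over WT, the NF-kB and inflammatory list had a median log2 fold of 0.23 in fibroblast-like cells and -0.21 in endothelial-like cells. The difference of 0.45 between the 2 classes was not tested, and the endothelial median was 0.22 within the Gpihbp1-led clusters and 0.10 within the Selp-led cluster, so the opposite direction was absent there. For the same comparison, the dissociation and immediate early list had a median of 0.51 in endothelial-like, 0.39 in mural-like and -0.18 in LepR stromal-like cells. The difference was 0.70 between endothelial-like and LepR stromal-like cells and 0.58 between mural-like and LepR stromal-like cells, and neither was tested. This list also answers to the handling of tissue, which is not given per library in the sources used here.

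For aGVHD over BMT, the proliferation list had a median log2 fold of 0.73 in LepR stromal-like cells and -0.60 in endothelial-like cells. The difference of 1.32 was not tested. When cells were thinned to equal depth, which left out those under 2000 UMIs, the stromal value was -0.18 and the endothelial value 0.014. The stromal value was also -0.045 with a minimum of 2000 UMIs alone and -0.019 with doublets kept, and the endothelial value was 0.34 within the Gpihbp1-led clusters. The cause of these turns was not tested. The type I interferon response list had a median of 1.18 in fibroblast-like cells and -0.43 in LepR stromal-like cells. The difference of 1.61 was not tested.

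Called cells held 2353 UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in BMT and 3270 in aGVHD, against 0 in WT. All recipients and spleen donors are given as female, and the sex of the B6.SJL marrow donors is not given in the sources used here. Among neutrophil-like, B-lineage-like and erythroid-like cells of BMT, 660 carried Y-linked UMIs only and 10 carried Xist only, a ratio of 66, so male marrow donors are a likely source. In aGVHD, 1.67% of T and NK-like cells with either signal carried Y-linked UMIs only. These cells may therefore come from the spleen graft or the host, which this marker cannot separate. In BMT, given no spleen cells, 20 T and NK-like cells carried Y-linked UMIs only and 0 carried Xist only. The upper limit of that Xist-only share was 16.8%. Host-type T and NK-like cells were thus not seen among these few BMT cells. Whether such host cells remained in aGVHD was not tested. Among aGVHD cells of an unnamed cluster with Myb among its leading genes, 194 carried Xist only and 418 Y-linked UMIs only. The Xist-only share was 15.4 times that of BMT, with a lower bound of 4.76, while Xist in empty droplets was not higher in aGVHD, at 292 CPM against 383 CPM in BMT. This was not particular to that cluster. In aGVHD and BMT the Xist-only shares were 28.8% and 2.44% of erythroid-like cells with only 1 signal. They were 19.8% and 1.21% for neutrophil-like cells, and 88.9%, on 9 cells, and 2.22% for B-lineage-like cells. Megakaryocyte-like cells (30.6% and 19.2%) and mast or basophil-like cells (49.5% and 14.3%, on 7 BMT cells) had overlapping intervals.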

How the results depend on the processing

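No paired analysis was possible because each group had 1 library and no mouse was sampled in more than 1 group. Batch, handling and group cannot be separated for the same reason. Of the alternative settings for LepR stromal-like and endothelial-like cells, 14 were chosen before the data were examined and 4 after seeing the data. For named genes and lists, a value counted as the same when it lay within the interval of the main setting. It counted as turned only when that interval excluded 0. Lists whose interval held 0 could therefore change sign without being counted as turned. The adipogenic median in LepR stromal-like cells for aGVHD over BMT did so, running from -0.12 to 0.46 over the settings. For named genes, 676 of 767 values stayed the same, 89 moved and 2 turned direction. For lists, 1880 of 1955 values stayed the same, 64 moved and 11 turned direction. Clustering at resolution 0.5, a minimum of 20 UMIs per gene, and totals without mitochondrial and rRNA-derived genes moved none of them. Free-RNA subtraction moved 4 of them and median-of-ratios scaling 3, none of these a leading result. Free-RNA subtraction and the limit to members above the empty-droplet level were extended to fibroblast-like and mural-like cells after seeing the data. The limit gave no value for MHC class II in LepR stromal-like and endothelial-like cells and MHC class I in endothelial-like cells for BMT over WT, nor for the interferon and MHC lists of fibroblast-like and mural-like cells in that comparison. Across settings the interferon gamma response median in LepR stromal-like cells for BMT over WT stayed between 2.74 and 3.09. Where a value moved below, the cause was not tested.

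The settings that took endothelial clusters apart were added after seeing the data. With the Gpihbp1-led clusters only, 125 endothelial genes were higher for BMT over WT, the log2 fold of Gbp10 was -0.26 on 0 UMIs in WT, the NF-kB and inflammatory median 0.22 and the interferon gamma response median 1.64. For aGVHD over BMT the log2 fold of Sele was 1.21, which rests on the floor of 3 UMIs since BMT had 1 UMI and aGVHD 0, and the medians were 4.09 for MHC class II, 0.34 for proliferation and 0.52 for sinusoidal endothelium. With the Selp-led cluster only, 123 genes were higher and 94 lower for BMT over WT, and 176 were higher for aGVHD over WT. The MHC class II medians were 4.69 for BMT over WT, 1.26 for aGVHD over BMT and 5.99 for aGVHD over WT. The NF-kB and inflammatory median for BMT over WT was 0.10 and the p53 target median for aGVHD over WT 0.61. In the Selp-led cluster, which held 75 of 1229 aGVHD cells, the interferon gamma response median for aGVHD over BMT was 0.71. The Gpihbp1-led clusters split by library, so the cluster mix was not held fixed there. The part of cluster mix in the whole-class interferon value therefore stays open. The sinusoidal median for aGVHD over BMT was 0.27 in the Selp-led cluster, so the mix could account for the lower value of that list in the whole class. With list members above the empty-droplet level only, also added later, the endothelial interferon gamma response median for BMT over WT was 2.33.

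With at least 200 UMIs per gene, LepR stromal-like genes higher were 160 for BMT over WT, 90 for aGVHD over BMT and 228 for aGVHD over WT, and genes lower were 54, 204 and 232. Endothelial-like genes higher were 135 for BMT over WT, and genes lower were 76, 85 and 133. With cells thinned to equal depth, LepR genes higher were 154, 92 and 217, and 166 were lower for aGVHD over BMT. The proliferation medians became -0.18 for aGVHD over BMT and -0.22 for aGVHD over WT in LepR stromal-like cells, and 0.014 for aGVHD over BMT in endothelial-like cells. With the mean of each cell's CPM, the oxidative phosphorylation median in LepR stromal-like cells for aGVHD over BMT was -0.021.

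With at least 2000 UMIs per cell, the endothelial MHC class II median for aGVHD over BMT was 0.91 and the LepR proliferation median -0.045. The share ratios were 0.712 for LepR cells in aGVHD over BMT and 1.15 in aGVHD over WT, 4.96 for endothelial cells in BMT over WT and 1.31 in aGVHD over BMT, and 0.508 for fibroblasts in aGVHD over WT. With at least 500 UMIs and 250 genes, the LepR share ratios were 1.36 for BMT over WT and 0.797 for aGVHD over WT. With a UMI minimum set per library from its deepest barcodes, 167 endothelial genes were lower for aGVHD over WT and the MHC class II median for aGVHD over BMT was 1.17. LepR share ratios were then 2.26 for BMT over WT, 1.06 for aGVHD over BMT and 2.40 for aGVHD over WT, and endothelial ratios 5.44 for BMT over WT and 1.09 for aGVHD over BMT.

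With doublets kept, the endothelial MHC class II median for aGVHD over BMT was 0.91 and the LepR proliferation median -0.019. Share ratios were 3.58 for endothelial cells in BMT over WT and 5.07 in aGVHD over WT, 0.344 for fibroblasts in BMT over WT and 0.377 in aGVHD over WT, and 0.0105 for osteolineage cells in aGVHD over BMT and 0.0132 in aGVHD over WT. With under 20% mitochondrial UMIs, the endothelial ratios were 3.75 for BMT over WT and 5.45 for aGVHD over WT, and the fibroblast ratio for BMT over WT was 0.448. At resolution 2, LepR ratios were 1.29 for BMT over WT and 0.853 for aGVHD over WT, and fibroblast ratios 0.462 for BMT over WT, 0.776 for aGVHD over BMT and 0.359 for aGVHD over WT. With each library clustered alone, the LepR ratio for aGVHD over BMT was 0.555, and endothelial ratios were 1.25 for aGVHD over BMT and 5.13 for aGVHD over WT. Fibroblast ratios were 0.296 for BMT over WT and 0.305 for aGVHD over WT, and osteolineage ratios 0.746 for BMT over WT and 0.342 for aGVHD over BMT.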

Other observations

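Haematopoietic cells that passed the depleting sort differed widely among the libraries and were not described above. B-lineage-like cells were 3.33% of all cells in WT, 6.74% in BMT and 0.188% in aGVHD, where 10 cells remained. Erythroid-like cells were 8.42% in WT, 2.53% in BMT and 20.4% in aGVHD. Megakaryocyte-like cells were 0.461% in WT, 1.54% in BMT and 4.23% in aGVHD. Mast or basophil-like cells numbered 14 of 6722 in WT, 8 of 3516 in BMT and 133 of 5320 in aGVHD. Neutrophil-like cells were 1.34% in WT, 21.5% in BMT and 12.4% in aGVHD. An unnamed cluster with Myb, a progenitor transcription factor gene, among its 20 leading genes held 33 cells in WT, 172 in BMT and 712 in aGVHD.

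T and NK-like cells were few, at 55 in WT, 25 in BMT and 64 in aGVHD. In them the interferon gamma gene Ifng was at 97.0 CPM in WT, 20.9 CPM in BMT and 198 CPM in aGVHD, on 38, 4 and 69 UMIs. Ccl5, a chemokine gene of effector T cells, was at 11128 CPM in WT, 13618 CPM in BMT and 16838 CPM in aGVHD. The granzyme genes Gzmb and Gzma were highest in WT, with Gzmb at 1079 CPM in WT, 256 CPM in BMT and 729 CPM in aGVHD, and Gzma at 975 CPM, 178 CPM and 491 CPM. Cd4 was at 53.6 CPM, 15.7 CPM and 115 CPM, and Cd8a at 255 CPM, 288 CPM and 261 CPM.

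The tests below were chosen after the result was seen. MHC class II genes in LepR stromal-like and endothelial-like cells of BMT and aGVHD could reflect free RNA in the droplets, but the lowest ratio of the level seen to the level expected from free RNA, with its share set by the upper bound of Y-linked UMIs, was 25.6. Leukocytes caught in the same droplets could add the same genes. However, 62.3% of LepR stromal-like cells in BMT and 84.7% in aGVHD held at least 3 UMIs of 4 MHC class II genes. The higher doublet share removed from these 2 libraries was 4.45%, which was preset at 0.8% per 1000 called cells and not measured. Scrublet's own threshold would have removed 35 cells from BMT and 78 from aGVHD. For endothelial-like cells the shares with at least 3 such UMIs were 21.2% in BMT and 30.9% in aGVHD, and co-capture was not tested there. In LepR stromal-like cells these values leave neither route as the main source, with co-capture judged against that preset share. Expression by those cells is a hypothesis whose inducer was not tested.

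The absence of Bglap-led osteolineage-like cells in aGVHD could come from losses when barcodes were called, but over all barcodes the higher of the Bglap and Col1a1 levels in aGVHD was 1.24% of that in BMT. Bglap over all barcodes was at 3336 CPM in WT, 7413 CPM in BMT and 16.3 CPM in aGVHD. A lower yield of bone-surface cells in the sort or dissociation cannot be told apart from a true absence with 1 sort per group. Postn-led cells were lower as well, at 1.61% (1.14 to 2.21) of named non-haematopoietic cells in aGVHD and 3.26% (2.54 to 4.12) in BMT. Loss of mature osteoblasts in aGVHD is a hypothesis that a second library or tissue sections could test.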
